A study of Homo sapiens with 6 samples.

How the data were processed

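BL-2, an established cell line from a Burkitt lymphoma, a cancer of germinal centre type B cells, was compared without treatment and after 6 h with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria. RNA of 3 control and 3 LPS samples was measured, each on its own Affymetrix array. Per the labels' protocols, RNA was purified on a commercial column and a biotin label was introduced by in vitro transcription. The labels name 3 samples of each group and do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be partly technical.

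The values analysed were the deposited table of 1 value per probe set and array. These deposited values were taken to be on the log2 scale, because 54675 probe sets per array lay between 5.46 and 14.81; the log base is inferred from that range. Which background correction, summary and normalisation made them is not given in the sources used here. The array medians were 6.45, 6.46 and 6.44 for controls 1 to 3, and 6.45, 6.47 and 6.42 for LPS 1 to 3. The arrays' distributions were close without being identical, and values were not centred per gene, so levels of different probe sets remain on each probe set's own scale. The direction of every change, LPS minus control, follows from the table's columns, each of which belongs to a labelled sample. The values show a floor near 5.5, and no detection calls were used, so fold changes of probe sets close to it may be compressed. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.063.

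The 62 Affymetrix control probe sets were left out of the tests, and 54613 were tested. Gene names came from the platform's annotation, brought up to date through gene identifiers with the RefSeq gene table of human assembly GRCh38.p14. Among tested probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Of those with 1 symbol, 41037 matched the RefSeq table, 54 did not, and 0 changed their symbol. The array values carry no genome positions and name no build, so no coordinates are given. A gene was represented by its probe set with 1 symbol and the highest mean over all 6 arrays, which gave 19775 genes. This choice was kept when an array was left out or the values were normalised again. Probe sets with several symbols were not named.

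The comparison was made in R 4.3.3 with limma 3.58.1: a linear model with group as its only term over all 6 arrays, moderated by empirical Bayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Intervals cover 95%. For gene lists, limma's camera was run on the representative probe sets with a preset correlation between genes of 0.01, and p-values were adjusted over the 29 lists. Lists needed at least 5 measured genes. Counts "adjusted over the list alone" use Benjamini-Hochberg over a list's own members. The same steps were tested on simulated arrays made from the real means and residual spreads of the 54613 probe sets, with LPS against control as the comparison. The changed probe sets were drawn from those above the median level. Of 100 probe sets changed by 0.6 on the log2 scale 75% were called, of 100 changed by 1 on that scale 96% were called, and 4 unchanged probe sets were called. A list of interferon response genes shifted by 0.3 was called by camera, with 0 other lists. All simulated probe sets varied independently and held no array sets, unlike the real ones. The shares called may therefore not hold for the real data or for dim probe sets.

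The lists, the test and the rule for naming genes were fixed before the data were examined. Named were 18 readouts of the LPS response chosen from general knowledge, of which 16 had a probe set with a single gene symbol here; the 10 largest rises and 10 largest falls among genes that passed the test with all LPS values on one side of all control values; and, for each list that camera called, the 4 members with the smallest unadjusted p. Genes named beyond that rule were chosen after their values were seen. Among the lists were markers of monocytes, of T and NK cells, of fibroblasts and epithelium, and of erythroid cells and platelets, which a B cell line should lack.

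Alternatives set beforehand were a block on the replicate number, quantile normalisation, median centring, filters on dim probe sets, the variance prior, array weights, other thresholds, leaving out probe sets whose suffix marks possible cross-hybridisation (_x_at and _s_at), the mean over a gene's probe sets, other list tests, and leaving out each array in turn. A block on array set was added after the data were seen. The sets were found from 18 probe sets for bacterial and phage transcripts added to every hybridisation: the arrays were ordered by their mean level of these and parted at the widest gap, 0.22 on the log2 scale, against 0.081 for the next widest. Set A held control 1, LPS 1 and LPS 2, and set B held control 2, control 3 and LPS 3.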

Results

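Gene expression was measured in BL-2 Burkitt lymphoma cells left untreated or exposed to LPS for 6 h, with 3 arrays per group. The comparison asks which transcripts differ after LPS, which in responsive cells is recognised by TLR4 with its partners MD-2 and CD14. Correlations between arrays over all probe sets ran from 0.992 to 0.997, and 0 values were identical between any 2 arrays. The arrays also fell into 2 sets by the level of the added hybridisation controls, 10.24 ± 0.045 (SD, n = 3) in set A and 10.57 ± 0.051 (SD, n = 3) in set B on the log2 scale. Set A held 1 control and 2 LPS arrays and set B 2 controls and 1 LPS array. Values within each set are therefore given beside the pooled ones for the called lists and for some genes. The 3' to 5' difference of GAPDH, a measure of RNA integrity, lay between 0.13 and 0.16 on all arrays. That of ACTB was 0.37 to 0.41 in set A and 0.44 to 0.48 in set B.

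**Figure D1:**
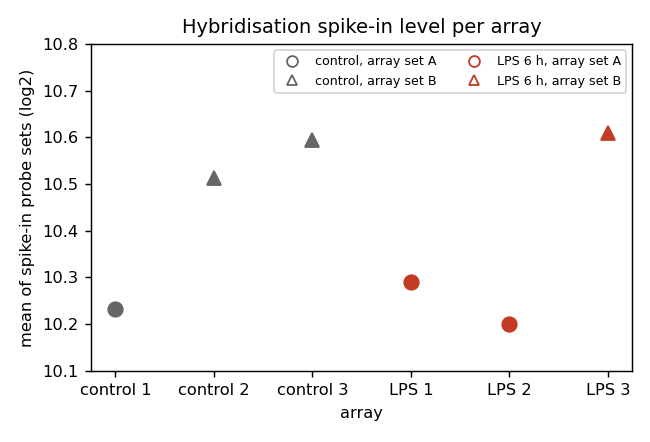
Mean log2 level of the 18 hybridisation spike-in probe sets (vertical axis) on each of the 6 arrays (horizontal axis), with controls in grey, LPS in red, set A as circles and set B as triangles. The sets are separated by a gap of 0.22, and each holds arrays of both groups.

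After LPS, 77 genes changed, 36 of them higher and 41 lower. The largest change was in ID1, an inhibitor of helix-loop-helix transcription factors, which fell by 1.90 on the log2 scale (SE 0.090, adjusted p = 3.3e-07, n = 3 per group), a level 3.73-fold higher in control than in LPS cells. The largest rise was that of IFIT3, an interferon-induced antiviral protein. From a control level of 6.45, near the array medians, it rose by 1.05 on the log2 scale or 2.07-fold (SE 0.064, adjusted p = 5.25e-06). This value and its rank rest on the brightest probe set: the other IFIT3 probe set rose by 0.54 (adjusted p = 0.0124), and the mean over both by 0.80. These were the 2 genes with a change of at least 2-fold, and 30 of the 77 changed by at least 1.5-fold.

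Counted by probe set, 144 passed the limma test, 71 higher and 73 lower, and 4413 had an unadjusted p under 0.05 where 2731 are expected by chance. In all 77 genes the 3 LPS values lay on one side of the 3 control values, which a test on these same values favours. Of all tested probe sets 13.4% were separated in this way, where chance gives 10%. The count rests on the arrays used: it was 374 probe sets without control 1, 46 without control 2 and 14 without control 3. It was 44 without LPS 1, 10 without LPS 2 and 120 without LPS 3. Without control 1 all controls left are in set B and most LPS arrays in set A, so differences between the sets can add to the 374. With array set as a block, a fit added after the data were seen, 734 probe sets passed, including all 144. That count was 102 without LPS 3, 185 without control 1 and 397 without LPS 1, with 64, 85 and 142 of the 144 kept.

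Beside IFIT3, the rises were led by LINC00158, a long non-coding RNA, at 0.95 (SE 0.069, adjusted p = 3.34e-05). CD58, the adhesion ligand of the T cell receptor CD2, rose by 0.83 (SE 0.10, adjusted p = 0.00556) by its brightest probe set, and 2 further probe sets of CD58 rose by 0.75 and 0.76. A pair of dim CD58 probe sets did not pass, at 0.04 and -0.03. CREM, a transcription factor of the cyclic AMP response, rose by 0.80 (adjusted p = 0.0173) by its brightest probe set. None of its 5 other probe sets passed, at -0.00084 to 0.33, and the mean over its probe sets was 0.30 (adjusted p = 0.0405). IKBKE, a kinase that acts on interferon regulatory factors and NF-kB, rose by 0.72 (adjusted p = 0.00735), and HLA-DQB1, an MHC class II chain, also by 0.72 (adjusted p = 0.0129). The others were MAN1A1, a Golgi mannosidase, at 0.78, RILPL2 at 0.78, the DNA glycosylase NEIL2 at 0.73 and UMODL1 at 0.72, with adjusted p from 0.0014 to 0.0334. Within the array sets these 10 rises ran from 0.46 to 0.95 in set A and from 0.68 to 1.14 in set B. The naming rule puts all LPS values on one side of all controls, so the same sign in both sets was fixed beforehand. Values within a set also rest on 1 control in set A and 1 LPS array in set B.

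The falls included further members of the ID family, ID3 at -0.81 (SE 0.12, adjusted p = 0.0126) and ID4 at -0.78 (SE 0.11, adjusted p = 0.00949). Of the other ID4 probe sets, that at -0.61 passed (adjusted p = 0.00756) and those at -0.40, -0.37 and -0.13 did not. RGS18, a regulator of G protein signalling, was at -0.85 (adjusted p = 0.0014), HMCES, which shields abasic sites in DNA, at -0.85 (adjusted p = 0.00846; other probe set -0.44, adjusted p = 0.0616), and CAB39L, related to a scaffold of the LKB1 kinase, at -0.80 (adjusted p = 0.00161). TXNIP, the thioredoxin-interacting protein, fell by 0.79 (SE 0.15, adjusted p = 0.0423), and its other probe sets, at -0.63 and -0.62, did not pass. By its brightest probe set TXNIP was at -1.19 within set A and -0.58 within set B, and its adjusted p was 0.177 without control 2, 0.216 without LPS 1, 0.232 without LPS 2 and 0.0795 without LPS 3. CCNG2, an atypical cyclin, was at -0.70 (adjusted p = 0.0107), with other probe sets at -0.72, -0.68 and -0.56, which passed, and at 0.03. TMT1A, a thiol methyltransferase, was at -0.80 (adjusted p = 0.00735), and none of its other probe sets passed, at -0.41 to -0.02. Leaving out probe sets marked for cross-hybridisation gave -0.02 (adjusted p = 0.975). A dim probe set, at a control level of 6.38 against 10.01 for the brightest, then represents TMT1A. FAM167A was at -0.67 (adjusted p = 0.00738), with 1 other probe set at 0.02. Within the array sets the 10 largest falls, ID1 included, ran from -1.82 to -0.55 in set A and from -1.90 to -0.58 in set B. Here too the naming rule fixed the shared sign.

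**Figure D2:**
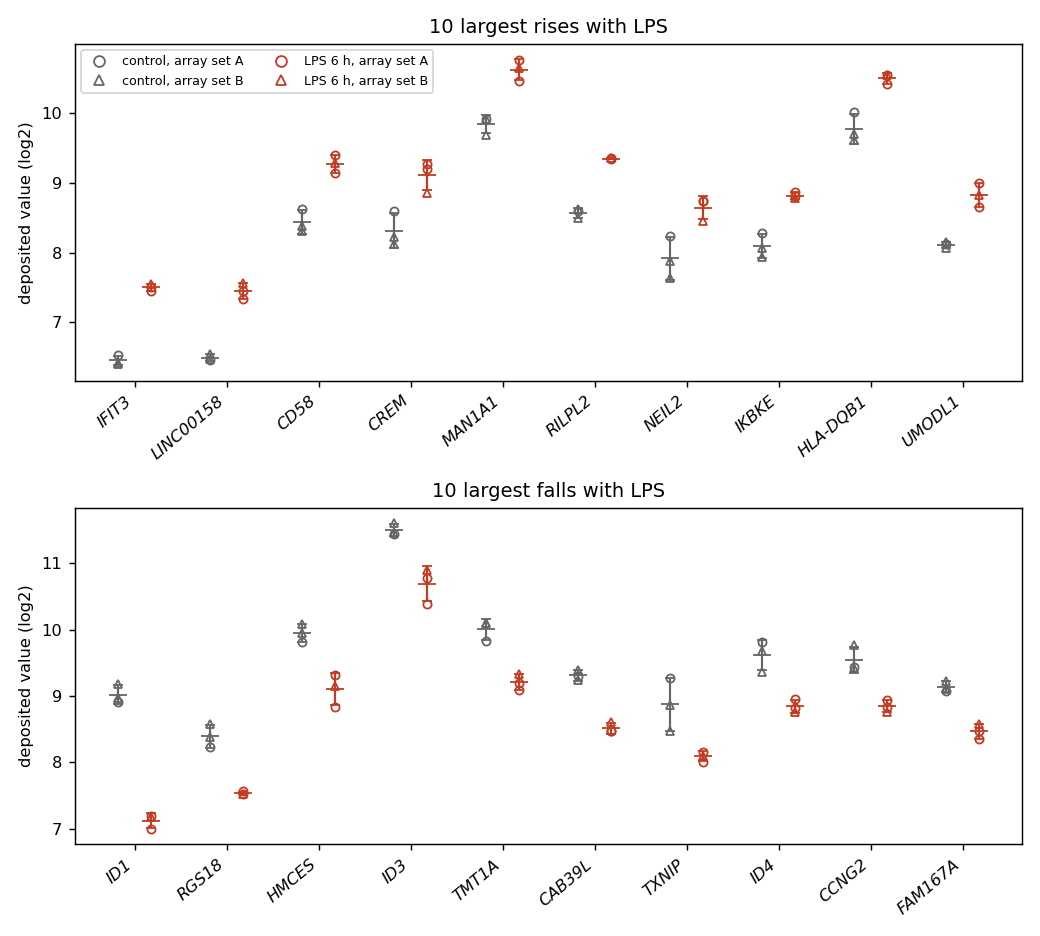
Deposited log2 values (vertical axes) of the 10 genes with the largest rise (upper panel) and the 10 with the largest fall (lower panel), 1 point per array, controls in grey and LPS in red, circles for set A and triangles for set B. Horizontal ticks with bars are means ± SD of 3 arrays. For each gene all LPS values lie on one side of all control values, which the naming rule required. ID1 was at 9.02 ± 0.15 in control and 7.12 ± 0.11 in LPS cells.

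Of the 16 measurable readouts of the LPS response 0 passed the limma test by their brightest probe set, 4 had an unadjusted p under 0.05, and ICAM1 passed by another probe set. The receptor TLR4 stood at 7.35 ± 0.15 in control and 7.25 ± 0.065 in LPS cells (SD, n = 3), a difference of -0.10 with a 95% interval from -0.28 to 0.07. Its partner MD-2, encoded by LY96, gave -0.12 and CD14 gave -0.11, at control levels of 6.58 and 6.25, where the array medians ran from 6.42 to 6.47. The adaptor MYD88 gave 0.01, and the related receptor pair CD180 and LY86 gave -0.13 and -0.07. MYD88 had values of -0.10 and -0.02 within the sets, and LY86 -0.14 and 0.06.

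Among readouts downstream of the receptor, IRF4, a transcription factor of plasma cell differentiation, had the largest difference at 0.58 (SE 0.12, adjusted p = 0.0852), with dimmer probe sets at 0.26 and 0.03. ICAM1, an adhesion molecule, gave 0.45 (adjusted p = 0.159), and its dimmer probe sets gave 0.48 (adjusted p = 0.0347) and 0.17 (adjusted p = 0.588). The value was 0.39 for TNFAIP3, a negative regulator of NF-kB (adjusted p = 0.0788). BCL6, the repressor that maintains the germinal centre state, gave -0.31 (adjusted p = 0.321). With array set as a block these 4 passed, with adjusted p of 0.00189, 0.0131, 0.0143 and 0.0467 in the same order. NFKBIA gave 0.16 with an SE of 0.19, and was -0.31 within set A and 0.27 within set B. TNF gave 0.07, CCL4 0.05, CD83 -0.04, EGR1 -0.14 (-0.39 within set A and -0.01 within set B) and MYC -0.06. In CCL4, CD83 and MYC, as in LY86 and NFKBIA, the 2 sets differed in sign.

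**Figure D3:**
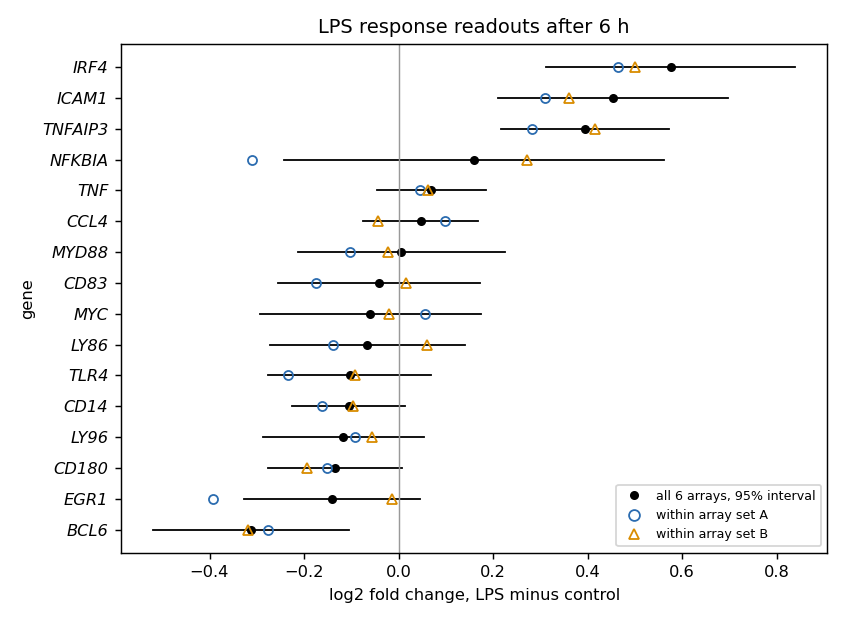
Log2 fold change, LPS minus control (horizontal axis), of the 16 readout genes (vertical axis): black points with 95% intervals use all 6 arrays, blue circles are differences within set A and orange triangles within set B. The intervals are not adjusted for the number of probe sets; those of IRF4, ICAM1, TNFAIP3 and BCL6 leave out 0, and of the probe sets shown, the brightest of each gene, none passed after adjustment.

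Of the 29 gene lists, camera called 9 shifted, 5 upward and 4 downward. With an estimated correlation between genes 0 were called, the lowest adjusted p being 0.531, with 1 list at an unadjusted p under 0.05. By fry, which asks whether a list's genes move one way without reference to other genes, 0 were called, with 6 at an unadjusted p under 0.05, and 14 changed in either direction. The other 9 splits of the 6 arrays into 3 and 3 gave 4 to 13 called lists by the same camera test. By size of the median, the real split ranked 1 of 10 for germinal centre, MHC class II, MYC and histone genes. Their medians were 0.26, 0.26, 0.14 and 0.065 in size, and the largest in another split 0.12, 0.25, 0.13 and 0.045. It ranked 2 for NF-kB targets, 3 for MHC class I and cholesterol genes, and 4 for hypoxia and ribosomal protein genes. With 10 splits no rank gives a share under 0.05.

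Germinal centre B cell genes were shifted down (28 measured, camera adjusted p = 3.72e-09, adjusted p = 0.531 with an estimated correlation). Their median was -0.26, with -0.26 in set A and -0.18 in set B. Of the members 22 lay below 0, 2 fell, and 13 fell when adjusted over the list alone. ID3 fell as given above, and MYBL1, a transcription factor of germinal centre cells, fell by 0.56 (adjusted p = 0.0288), with other probe sets at -0.03 and -0.05. STAP1, an adaptor of B cell signalling, was at -0.56 (adjusted p = 0.0675), with its other probe set at -0.51 (adjusted p = 0.0422), and the transcription factor IRF8 at -0.43 (adjusted p = 0.13). With array set as a block 12 members fell.

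MHC class II genes were shifted up (16 measured, adjusted p = 1.16e-06, adjusted p = 0.531 with an estimated correlation), with a median of 0.26, and of 0.10 in set A and 0.42 in set B. Set B minus set A gave a median of -0.14 over all arrays, whatever their group. With array set as a block the LPS median was 0.27. HLA-DQB1, HLA-DQA1 (0.59, adjusted p = 0.0309) and CIITA, the transactivator of class II genes (0.40, adjusted p = 0.0316), rose. The other probe sets of CIITA, at 0.10 and 0.15, did not pass. Adjusted over the list alone, 8 rose and 1 fell. HLA-DOA was at 0.53 (adjusted p = 0.0578), and its 4 other probe sets, at -0.01 to 0.29, did not pass. MHC class I and antigen processing genes were also shifted up (19 measured, median 0.14, adjusted p = 5.02e-05, adjusted p = 0.575 with an estimated correlation), with medians of 0.09 and 0.20 in sets A and B. For this list set B minus set A gave a median of -0.18 over all arrays. With LPS in the fit camera did not call that difference (adjusted p = 0.143). With array set as a block the LPS median was 0.13 (camera adjusted p = 3.41e-06). HLA-C rose by 0.49 (adjusted p = 0.0368) and HLA-E by 0.54 (adjusted p = 0.0403; other probe sets 0.30 and 0.42, not passing), and 8 rose when adjusted over the list alone. The peptide transporter TAP1 was at 0.36 (adjusted p = 0.104) and HLA-B at 0.41 (adjusted p = 0.131), with its dimmer probe sets at 0.51 (adjusted p = 0.0326) and 0.47 (adjusted p = 0.0791). HLA probe sets can cross-hybridise, and without probe sets marked for it the class I list had an adjusted p of 0.142.

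NF-kB target genes were shifted up with 0 single members passing (40 measured, 29 above 0, median 0.08 overall and 0.07 in each set, adjusted p = 4.93e-05, adjusted p = 0.531 with an estimated correlation). With array set as a block the median was 0.05 (adjusted p = 2.38e-05). The list was lower in set B than in set A by a median of 0.08, and with LPS in the fit camera did not call that difference (adjusted p = 0.0812). Adjusted over the list alone 8 rose, and without probe sets marked for cross-hybridisation the list's adjusted p was 0.0907. The inhibitor NFKBIE was at 0.49 (adjusted p = 0.0572), the kinase MAP3K8 at 0.29 (adjusted p = 0.0853; other probe set 0.07) and the survival gene BCL2A1 at 0.39 (adjusted p = 0.132). MYC and ribosome biogenesis genes were shifted up (34 measured, 27 above 0, median 0.14, adjusted p = 5.02e-05, adjusted p = 0.607 with an estimated correlation), with 0 members passing, also over the list alone. Their medians were 0.05 in set A and 0.22 in set B, and the leading members LYAR, WDR43, UTP20 and POLR1B lay between 0.29 and 0.37. Cholesterol synthesis genes were shifted up (21 measured, 18 above 0, median 0.12, adjusted p = 0.000954, adjusted p = 0.649 with an estimated correlation), with 2 rising over the list alone. Their medians were 0.26 in set A and 0.04 in set B, and without control 1 the adjusted p was 0.123. Another split of the arrays gave a median of 0.21 in size, and the split between the array sets 0.007. LSS, which makes lanosterol, was at 0.50 (adjusted p = 0.142; other probe sets 0.05 and 0.34), SQLE at 0.35, HSD17B7 at 0.32 and ACAT2 at 0.25.

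Hypoxia and glycolysis genes were shifted down with 0 single members passing (30 measured, 28 below 0, median -0.12, adjusted p = 4.39e-09, adjusted p = 0.531 with an estimated correlation). The median was -0.02 in set A and -0.17 in set B. The list was higher in set B than in set A by a median of 0.20, taken over all arrays of each set whatever their group. With LPS in the fit and the preset correlation, camera called the list higher in set B (adjusted p = 1.31e-08). Adjusted over the list alone 9 fell. PFKFB4, a regulator of glycolysis, was at -0.71 (adjusted p = 0.0556), the histone demethylase KDM3A at -0.69 (adjusted p = 0.0538), the collagen hydroxylase P4HA1 at -0.59 (adjusted p = 0.0914) and the MYC antagonist MXI1 at -0.44 (adjusted p = 0.0616). PFKFB4, KDM3A and P4HA1 each have 1 dimmer probe set, at -0.03, 0.07 and 0.01. By their brightest probe sets they were at -0.32, -0.34 and -0.30 within set A and at -0.92, -0.91 and -0.77 within set B. Replication-dependent histone genes were shifted down (26 measured, 20 below 0, median -0.06, adjusted p = 0.00126, adjusted p = 0.531 with an estimated correlation), with medians of -0.07 and -0.05 in sets A and B and an adjusted p of 0.0511 without LPS 1. Of these 1 fell over the list alone, and H2AC6, H2BC5, H1-2 and H4C4 lay between -0.27 and -0.14, with another H2BC5 probe set at -0.06. The control levels of these named genes were low, at 6.54 to 7.01, where the array medians ran from 6.42 to 6.47. Of the 26 members 11 were left by the filter for probe sets above the median level, and camera still called them lower (adjusted p = 0.00336). Ribosomal protein genes had a median of -0.14 (29 measured, 28 below 0, 0 passing also over the list alone, adjusted p = 0.00136, adjusted p = 0.900 with an estimated correlation). The list was higher in set B than in set A by a median of 0.38. The median LPS difference was -0.07 in set A and 0.04 in set B, and with array set as a block -0.01 with an adjusted p of 0.849. With quantile normalisation the adjusted p was 0.256. Their examples RPL32, RPS9, RPS10 and RPL3 were at -0.18, -0.17, -0.18 and -0.15.

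**Figure D4:**
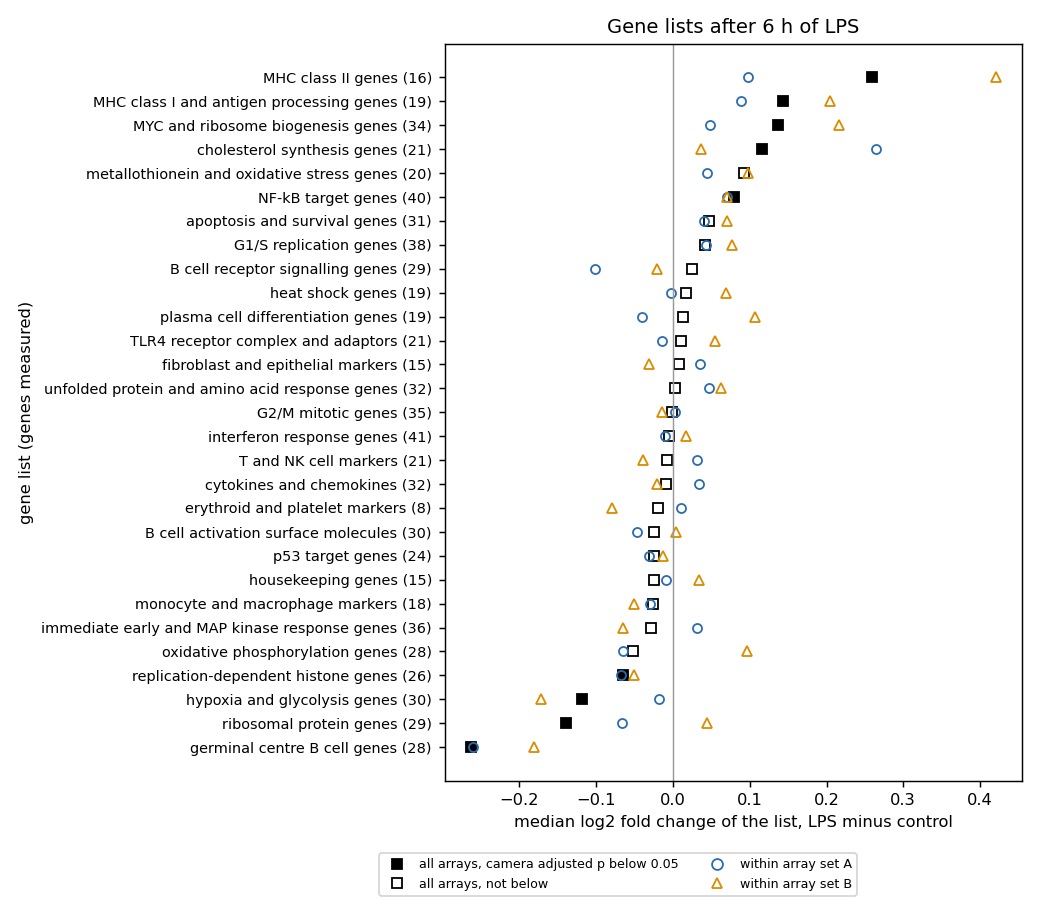
Median log2 fold change, LPS minus control (horizontal axis), of each of the 29 gene lists (vertical axis, genes measured in brackets). Black squares use all arrays and are filled where the camera adjusted p was below 0.05, blue circles are set A and orange triangles set B; germinal centre genes lie lowest at -0.26 and MHC class II genes highest at 0.26.

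Interferon response genes were not shifted as a list (41 measured, median -0.01, adjusted p = 0.954) and held changes in both directions, with a fry adjusted p for either direction of 1.63e-08. Among the 15 members left by the stricter filter on dim probe sets, which leaves out IFIT3 and IFIT1, camera called the list lower (adjusted p = 1.67e-05). IFIT3, IFIT1 (0.47) and IFI44 (0.33) rose, and TRIM22, an antiviral ubiquitin ligase, fell by 0.57 (adjusted p = 0.0245). The control levels of IFIT3, IFIT1 and IFI44 were low, at 6.45, 5.98 and 6.14, where the array medians ran from 6.42 to 6.47. That of TRIM22 was 9.82. Adjusted over the list alone 6 rose and 7 fell. Other lists that camera did not call held 5 more single changes. MT1X, a metallothionein, rose by 0.44 and TXNIP fell in the list of metallothionein and oxidative stress genes (20 measured, median 0.09, adjusted p = 0.0788). ELL2, an elongation factor of antibody-secreting cells, rose by 0.54 among 19 plasma cell differentiation genes (adjusted p = 0.21). DNAJB1 rose by 0.54 among 19 heat shock genes (adjusted p = 0.821), and CD58 among 30 B cell activation surface molecules (adjusted p = 0.895). In the remaining lists 0 members passed. Adjusted over the list alone, 3 rose and 6 fell among B cell receptor signalling genes, 3 rose and 1 fell among surface molecules, 2 rose and 1 fell among apoptosis genes, unfolded protein response genes and plasma cell genes each, and 1 rose and 2 fell among p53 targets. By the same count 1 rose and 1 fell among heat shock genes and among metallothionein and oxidative stress genes, 1 rose among immediate early genes, and 1 fell each among TLR4 receptor genes and T and NK cell markers. Camera gave an adjusted p of 0.678 for the 21 genes of the TLR4 receptor complex, 0.763 for 32 cytokines and chemokines, 0.191 for 36 immediate early genes and 0.593 for 29 B cell receptor signalling genes. The value was 0.131 for 38 G1/S and 0.678 for 35 G2/M genes, 0.232 for 28 oxidative phosphorylation genes, 0.308 for 31 apoptosis and survival genes, 0.433 for 24 p53 targets, 0.678 for 32 unfolded protein response genes and 0.678 for 15 housekeeping genes. Some of these lists were called under other settings. G1/S genes were higher with array set as a block (adjusted p = 0.00138, and 0.613 with an estimated correlation), and oxidative phosphorylation genes were lower with quantile normalisation (0.0415) and with array weights (0.0103). The p53 targets were lower without probe sets marked for cross-hybridisation (0.00218, 16 genes), and housekeeping genes were lower without LPS 3 (0.00848). An estimated correlation was not tried in these other settings. Housekeeping and oxidative phosphorylation genes were each higher in set B than in set A by a median of 0.20. With array set as a block their medians were 0.03 and 0.003, and camera called neither list (adjusted p = 0.228 and 0.395). Markers of other cell types gave 0.308 for 18 monocyte and macrophage genes, 0.593 for 21 T and NK cell genes, 0.678 for 15 fibroblast and epithelial genes and 0.678 for 8 erythroid and platelet genes.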

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

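The array set block, alone, with an estimated correlation and with each array left out, was chosen after the data were seen; the other alternatives were set beforehand. Against 144 probe sets (71 higher, 73 lower), 77 genes and 9 lists, the replicate block, with the number in the sample titles as a term, gave 498 probe sets, 264 higher and 234 lower, and 270 genes. The deviations of arrays with the same number correlated at 0.44, -0.04 and 0.23, and not every array correlated best with its own number. Control 2 and LPS 2 lie in different array sets, so these values do not settle whether the numbers pair the samples. The labels do not say what a shared number means. Quantile normalisation gave 292 probe sets, 121 higher and 171 lower, and 167 genes, and 143 of the 144 remained. Array weights gave 309 probe sets, 173 higher and 136 lower, and 163 genes. Without an intensity trend 110 probe sets were higher and 122 genes changed. Leaving out probe sets marked for cross-hybridisation, so that fewer were tested, gave 82 probe sets, 41 higher and 41 lower. An adjusted p below 0.1 gave 265 probe sets, 132 higher and 133 lower, and 142 genes. A fold of at least 1.5 gave 55 probe sets, 33 higher and 22 lower, and 30 genes. The array set block gave 734 probe sets, 343 higher and 391 lower, and 400 genes, including all 77. For lists, an estimated correlation gave 0, fry in one direction 0, fry in either direction 14, and the array set block with an estimated correlation 0. Median centring, both filters on dim probe sets, the robust prior and the mean over a gene's probe sets kept every count within 1.5 times. The number of lists hides changes of members: with camera's preset correlation 4 of the 9 lists kept their call in all settings run, and 5 of the other 20 were called in some. Under the stricter filter on dim probe sets interferon response genes were called, and histone genes had too few members to be tested. G1/S genes were also called without control 3 (0.0308) and without LPS 2 (0.000295), and oxidative phosphorylation genes without control 1 (0.032) and without LPS 3 (5.12e-06). Leaving out control 1 or LPS 3 makes the spread of the groups over the array sets more uneven, and oxidative phosphorylation genes differed between the sets. The robust prior does not enter camera, so the list results cannot change with it. Where no reason is given here, the cause was not tested.

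Leaving out 1 array at a time, with the spread pooled over the 5 that remain, gave 10 (without LPS 2) to 374 (without control 1) probe sets, 5 to 216 higher, 4 to 158 lower, 6 to 201 genes and 7 to 11 lists. Without control 3 it was 14 probe sets, of which 13 were among the 144, and without LPS 2 9 of the 10 were. With the array set block the same step gave 102 (without LPS 3) to 744 (without control 2) probe sets, with 185 without control 1, 629 without control 3, 397 without LPS 1 and 695 without LPS 2. Without control 1 set A had no control left, and without LPS 3 set B had no LPS array. Of the 25 named genes that passed, 6 passed under all settings tried on them (IFIT3, LINC00158, RILPL2, ID1, RGS18 and CAB39L), and of the 44 that did not pass, 20 passed under at least 1 setting. Signs were reversed for 8 named genes. CD58 was at -0.033, P4HA1 at 0.0086 and RPS9 at 0.035 without probe sets marked for cross-hybridisation, which leaves a dimmer probe set to represent each. MYD88 was at -0.054 with quantile normalisation, at -0.047 without control 2, -0.023 without control 3 and -0.047 without LPS 1 (0.088 without control 1), and at -0.063 with the array set block. NFKBIA was at -0.019 and MYC at 0.017 with that block, and MYC at 0.032 without control 3 (-0.149 without control 1). LY86 was at 0.014 without LPS 2 (-0.126 without LPS 3), and CD83 at 0.0079 with array weights and 0.029 without control 1 (-0.138 without control 3). Signal over background limits dim genes: changes of probe sets whose level is close to the lowest value, 5.46, may be reduced.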

Other observations

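Chosen only after their results were seen were the count of splits for all changed probe sets, the tests of array set on the changed probe sets and on the hypoxia and ribosomal lists, the values of these lists at the level of arrays, the rank of the spike-in split, the oxygen and nutrient test, and the checks of the FOXO and BMP lists over splits and over assignments within the array sets. With array set as a block, a fit likewise added later, B cell receptor signalling genes moved in both directions. The phosphatase PTPRC (CD45) was at -0.53 in set A and -0.57 in set B (blocked adjusted p = 0.000167), the receptor chain CD79A at -0.39 and -0.31 (0.0103), PLCG2 at -0.38 and -0.32 (0.00858) and the inhibitory receptor FCGR2B at -0.37 and -0.26 (0.0121). CR2, the complement receptor CD21, was at 0.26 and 0.34 (0.00572) and PIK3CD at 0.35 in both sets (0.0141). These genes were chosen after their values were seen, and 0 of them passed without the block.

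In the same fit the NF-kB targets NFKBIZ (0.39 with the block, adjusted p = 0.0247) and GADD45B (0.40, 0.0101) were higher, as was the chaperone HSPA5 (0.37, 0.00638), while CD86, a costimulatory ligand, was lower (-0.38, 0.00758). TP53INP1 was at -0.67 (4.43e-05). Among interferon response genes OAS2 (-0.43, 0.00183) and IFITM1 (-0.36, 0.0485) were lower beside the rise of IFIT3 and IFIT1. NFKBIZ, GADD45B, HSPA5, CD86, TP53INP1, OAS2 and IFITM1 did not pass without the block, and were likewise chosen after their values were seen. Among called genes outside the lists, BATF, a transcription factor of activated lymphocytes, rose by 0.70, the OX40 ligand TNFSF4 by 0.38, and SMAD1, a mediator of BMP signals, fell by 0.59.

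There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. For changed probe sets 2 of the 10 splits gave at least the real 144, and the highest other count was 1580; with the larger direction of each other split as the comparison, it was 2 splits for higher probe sets, 71 against 1098, and 2 for lower ones, 73 against 1098, and for genes 2 splits, 77 against 497. That other split is the one between the array sets, which points to a structure of the arrays, and the other 8 splits called 0 probe sets. For lists 5 of the 10 splits called at least the real 9, and the highest other count was 13.

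The sets of arrays are the first pattern. With the block the log2 fold changes of the changed probe sets kept a median of 0.98 of their size, with a 5th percentile of 0.885. That cannot test an uneven spread of LPS and control over the sets as their cause. A difference between the sets also widens the spread within each group, so the pooled fit would hardly call probe sets moved by it. The hypoxia list had a median of -0.109 with the block against -0.118 without, and camera still called it (adjusted p = 9.85e-07). The spread between arrays leaves the cause open: the blocked mean over its genes was -0.18 with a 95% interval from -0.52 to 0.16. The blocked median was -0.035 without control 2 and -0.018 without LPS 3, where set B had no LPS array. It was -0.172 without control 1, where set A had no control, -0.137 without control 3, -0.139 without LPS 1 and -0.101 without LPS 2. The p with an estimated correlation, 0.214 with the block and 0.0916 without, decides nothing. The ribosomal protein list went from -0.14 to -0.0134 with the block, as an uneven spread predicts. For the sets themselves, a difference in hybridisation or scanning is a candidate cause, since the spike-in split ranked 1 of 10 by called human probe sets. Spike-ins added to the hybridisation cannot show a difference in labelling. The ACTB 3' to 5' difference also parted the sets, at 0.37 to 0.41 in set A and 0.44 to 0.48 in set B. Labelling, a stretched intensity scale or a difference between cultures in oxygen or nutrients may also contribute. These causes cannot be told apart. Quantile normalisation left 43.7% of the count between the sets (691 of 1580). The hypoxia list then differed by 0.0725, with a camera p of 0.401 with an estimated correlation.

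The joint fall of ID1, ID3, ID4 and SMAD1 is the second pattern, and lower BMP and SMAD1/5 signalling is a possible explanation. Of a separate list of BMP and SMAD1/5 targets without these genes, 17 lay above the median level, and their median of -0.0132 with the block lay at percentile 40.9 of 10000 random lists matched on mean level. Without the block the median was 0.017 at percentile 64.5, and it ranked 8 of 10 splits by size. ID2 (-0.49 with the block, adjusted p = 0.00155) and SMAD9 (-0.32, 0.036) were lower and the others did not pass, so members that go both ways leave the hypothesis open.

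The lower values of TXNIP and CCNG2, with BCL6 lower under the block, are the third pattern, and lower activity of FOXO transcription factors, which activate these genes, may account for it. On a separate list of 24 FOXO targets the median with the block was -0.13, with 19 below 0 and 6 passing, among them IL7R, KLHL24 and GADD45A, and it lay at percentile 0.01 of 10000 random lists, the smallest they can give. That percentile does not decide. With the block kept and the LPS label moved within each array set, 7 of 9 assignments, the real one included, put the list below the 5th or above the 95th percentile of random lists. The real one gave the largest median, but 9 are too few for a share under 0.05, and the others hold part of the real LPS difference. In the fit without the block, with 1000 random lists each, 6 of the 10 splits lay beyond the same limits. With the block and an estimated correlation camera gave a p of 0.00904. The estimate was negative here, at -0.0313, so this p carries no allowance for genes that move together. Without the block 0 of the 24 targets passed. The list's unblocked median of -0.08 lay at percentile 0.06 and ranked 5 of 10 splits by size, the largest being 0.10 between the array sets. Which upstream signal would lower both groups of genes was not tested.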
